A study of Homo sapiens with 3 samples.

How the data were processed

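The series profiled chromatin in SKOV3 cells by CUT&Tag, in which an antibody-tethered transposase cuts and tags DNA next to the antibody's target. The 3 libraries carry the titles Control, 2DG and IgG, with 1 library per group. The Control and 2DG libraries each have an annotated peak list and a tally of its annotation classes, and the IgG library was not analysed here. Groups were taken from the sample titles. The series title names a different compound (paeonol) from the design text and sample titles (2DG), the treatment text of the Control sample also reads 2DG, and the labels do not name the antibody's target. The labels do not spell out 2DG, which is the usual abbreviation of 2-deoxyglucose, a glucose analogue that blocks an early step of glycolysis. No other sample or group information was used.

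Per the file headers, the peaks came from a folder of MACS2 output named for a q of 0.05, as narrowPeak intervals, and were annotated with HOMER annotatePeaks.pl against an hg38 Ensembl sequence and gene annotation. The submitters' processing notes also name hg38. The aligner, the treatment of duplicate reads, the use of the IgG library as a background and the versions of these tools are not given in the sources used here. Peaks were called per library and not on pooled samples, since each library has its own list. The score of each peak is the authors' deposited value from the peak caller: by MACS2's convention for that column it is 10 times −log10 of q, and the lowest score in both lists was 13, as a q of 0.05 gives. The score was used only to describe, rank and filter peaks within a list, because it depends on depth. Neither list holds a fold enrichment or read count, so the depth of the libraries is unknown. The deposited tallies equalled the class counts of the lists in every class.

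All peaks lay on the main chromosomes, and no peak overlapped another of its list. A promoter peak of a protein-coding gene was a peak whose nearer edge lay within 1000 bp of the nearest annotated transcription start site (TSS), by the deposited distance. A peak counted only for the gene of its nearest TSS, and starts of alternative transcripts inside a gene counted as TSSs. A promoter peak can thus lie far from both ends of its gene. Genes were matched to 20037 coding genes of a RefSeq table of GRCh38.p14 by symbol or older symbol on the same chromosome. Genes with a promoter peak that had no match numbered 59 in Control and 204 in 2DG. Intervals were compared with bedtools, with an overlap of at least 1 bp counting as shared. The chance level was the mean of 100 random placements of the peaks on their own chromosomes, and of 100 moves of each peak by 2 to 20 kb. Peaks near gene ends were set against peaks moved by 20 to 200 kb. Placements used the span of each chromosome and did not leave out unmappable sequence.

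The 25 gene lists, with 495 genes, were fixed before the data were examined. Each list's share of genes with a promoter peak was placed among 10000 random lists of the same size, as a percentile with ties split. Shares above the 97.5th percentile are called high and those below the 2.5th low. The share found only in 2DG was taken among genes without a Control promoter peak. The share found only in Control was taken among genes with one, matched on 10 classes of the Control peak score. These percentiles describe the 2 libraries and are not p-values. On simulated lists of 20 genes over 20037 genes, 1.5% of 200 lists with no effect and 96% of 200 lists with a true share of 90% were called high for 2DG. A true share of 75% was called high in 44%. The lists with no effect were drawn from the same genes as the random lists, so their low rate follows from the method. It does not show how often a curated list would be called high without an effect. The overlap step recovered 200 of 200 planted overlaps with 0 false hits.

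The genes named were set by a rule written beforehand. It took the 10 genes with the strongest promoter peak in each list, the 10 strongest found only in Control, the 10 strongest found only in 2DG, 2 to 4 genes of each gene list, and loci known for their copy number or loss in SKOV3. Some genes that the rule takes are not reported here. Fold enrichment was the first choice for ranking and the score took its place. The peaks inside ACSS2, the receptor segments, the sites strong in both lists and the peak widths were picked after their values were seen.

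With 1 library per group no test between conditions was made and no p-value is given. Shares of peaks have Wilson intervals at 95%, which cover counting error only. Alternatives fixed beforehand were a score of at least 50, the same number of strongest peaks from each list, overlap of 50% of both peaks or a distance within 1000 bp, merged peaks, all sequences, the distance to the TSS in place of the annotation class, a promoter of 3000 bp and distances from the middle of a peak. Added after seeing the data were peaks wider than the minimum width and random lists matched on gene length or on the number of RefSeq transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. No genome sequence was used here, so GC content and repeats were not examined.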

Results

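CUT&Tag was performed on SKOV3, an established human ovarian carcinoma cell line, with 1 Control library and 1 library from cells treated with 2DG for 24 h. The comparison asks where in the genome the 2 libraries differ in their enriched sites. The third library, IgG, was not analysed here. The lists held 74776 peaks in Control and 189525 peaks in 2DG, and the depth of the libraries is unknown. There were no replicates, so differences between the lists are differences between 2 libraries, and neither a spread between replicates nor a background level is available for them. Coordinates are hg38.

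Promoter peaks were found at many more genes in 2DG than in Control. Of 20037 protein-coding genes, 11551 (57.6%) had a promoter peak in 2DG and 3485 (17.4%) in Control. Both lists had one at 2627 genes, 8924 genes had one only in 2DG, 858 only in Control and 7628 in neither. Of the genes with a Control promoter peak, 75.4% also had one in 2DG, against 53.9% of the genes without. The 2627 genes in common were 1.31 times the 2009 expected from independent lists and 1.26 times the 2079 expected after matching on gene length. They rarely had the same peak, as 202 Control promoter peaks of coding genes touched a 2DG peak. With the same number of strongest peaks from each list, 7504 genes had a promoter peak in 2DG and 1583 had one only in Control. Among peaks wider than the minimum width, 105 genes had one in Control, 5292 in 2DG and 43 in both. A promoter of 3000 bp gave 6237 genes in Control and 5017 in both. Control peaks lay within 1000 bp of an end of a coding gene only 1.19 times as often as the same peaks moved by 20 to 200 kb, against 2.17 times in 2DG. A single gene with a Control promoter peak therefore says little about that gene.

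ACSS2 (ENSG00000131069), which makes acetyl-CoA from acetate, and FADS1 (ENSG00000149485), a fatty acid desaturase, had the strongest promoter peaks in both lists. The ACSS2 peak scored 542741 in Control (chromosome 20, 34919432 to 34919581, class transcript end) and 11501103 in 2DG (34920846 to 34921635, class promoter). Both lay inside the gene and counted through starts of alternative transcripts there. Whether the ACSS2 peaks come from the chromosome or from spliced sequence outside it stays open, as given below. The FADS1 peak lay on an exon on chromosome 11, at 61804434 to 61804456 with a score of 39692 in Control and at 61804405 to 61804484 with a score of 639876 in 2DG. It too lay inside the gene and counted through a start of an alternative transcript there. It was 1 of 10 narrow sites outside ACSS2 that were strong in both lists, given below, and their origin was not tested. Below these 2 genes the lists diverged. The next strongest in Control were ZNF200 (10609), the circadian clock gene PER2 (8902), RTTN (8125), the PCNA-associated factor PCLAF (7498), TMEM268 (7431), the calcium release channel gene ITPR1 (6213), the splicing factor gene PRPF39 (6056) and COX7A2L (5619). In 2DG they were RNF213 (2961), STRN4 (2488), the translation elongation factor gene EEF1A1 (2308), RRP12 (2279), PDE9A (2106), MOCS3 (2063), SELENOS (1979) and TNS2 (1915). PER2 had a 2DG score of 221, TMEM268 of 170, ITPR1 of 97 and COX7A2L of 85, and in the other direction EEF1A1 had a Control score of 1381, STRN4 of 1903 and TNS2 of 1225. Scores of the 2 lists are on scales set by each library and were not divided by each other. The peaks of PER2, TMEM268, ITPR1, COX7A2L, STRN4 and TNS2 also lay inside their genes and counted through starts of alternative transcripts.

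The 10 strongest genes found only in Control were ZNF200, RTTN, PCLAF, PRPF39, ATF7IP (5130), RIBC2 (4887), MIPOL1 (4626), the galectin gene LGALS2 (4585), RALGAPB (3897) and AASS (3796), an enzyme of lysine breakdown. Their peaks were 22 to 42 bp wide. With distances to the TSS counted as negative upstream, the ZNF200 peak lay at -690 bp on chromosome 16 (3228483 to 3228507), the PCLAF peak at 272 bp on chromosome 15 (64387398 to 64387426) and the RTTN peak at 10 bp on chromosome 18 (70131912 to 70131933). The ZNF200 and RTTN peaks lay inside their genes, away from both ends, and counted through starts of alternative transcripts there. So did the peaks of PRPF39, ATF7IP, RIBC2, MIPOL1, RALGAPB and AASS. The 10 strongest found only in 2DG were RNF213, the ribosome biogenesis gene RRP12, the cGMP phosphodiesterase gene PDE9A, MOCS3, the selenoprotein gene SELENOS, P2RX6 (1814), SEPTIN2, the zinc transporter gene SLC30A4 and the lysosomal channel gene TPCN2 (1730 each) and the adiponectin receptor gene ADIPOR2 (1715). The RRP12 peak lay at 14 bp from a TSS on chromosome 10 (97373552 to 97373606), the SELENOS peak at -28 bp on chromosome 15 (101277472 to 101277585) and the ADIPOR2 peak at -174 bp on chromosome 12 (1690818 to 1690975). The RRP12 peak lay at such an alternative start inside its gene, as did those of RNF213, PDE9A, P2RX6 and TPCN2. RNF213 and ADIPOR2 had a Control promoter peak too when the promoter was taken as 3000 bp. Among peaks wider than the minimum width, AASS, LGALS2, RALGAPB, RIBC2, RTTN and TMEM268 had no promoter peak, ITPR1 and COX7A2L had one only in Control and STRN4 and TNS2 only in 2DG.

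Glycolysis genes stood out among the gene lists. A 2DG promoter peak was present at 22 of 23 glycolysis genes, against 57.7% of genes in random lists (percentile 99.995), and all 15 genes without a Control promoter peak had one in 2DG (8 of 15 with equal numbers of peaks, percentile 93.5, below the limit for a high share). The liver and platelet phosphofructokinase genes PFKL (613) and PFKP (520) had a peak only in 2DG, the lactate exporter gene SLC16A3 scored 583 in 2DG and had peaks in both lists, and the hexokinase gene HK2 had one only in Control (195). These peaks of PFKL, SLC16A3 and HK2 lay inside the genes and counted through starts of alternative transcripts there, while the PFKP peak lay just outside its gene. Control also had a high share of this list, 8 of 23 genes (percentile 97.7), which was lost with random lists matched on RefSeq transcripts (96.3). In sterol and fatty acid synthesis, 15 of 17 genes had a 2DG promoter peak and 3 a Control one (2DG percentile 99.6). The strongest were ACLY (433), which makes cytosolic acetyl-CoA, the squalene synthase gene FDFT1 (342) and FASN (277), and SCD and ELOVL6 had a peak in neither list. The ACLY peak lay inside its gene too. The call of the sterol and fatty acid list was lost among peaks wider than the minimum (96.5).

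Oxidative phosphorylation showed the opposite. Only 6 of 23 genes had a 2DG promoter peak (percentile 0.185) and 4 had a Control one, with none in common and 13 in neither list. The 4 Control genes were COX4I1 (1935), ATP5F1A (1379), ATP5F1B (1118) and ATP5PO (49), a share without a 2DG peak at percentile 99.8, and the strongest 2DG genes were COX5B (276) and UQCRC1 (152). That Control share was no longer high with a promoter of 3000 bp, where 1 of 6 Control genes lacked a 2DG peak (percentile 45.6), or among peaks wider than the minimum, where 1 Control gene was left (75.4). The strongest peaks of the 4 Control genes lay inside the genes and counted through starts of alternative transcripts there. The UQCRC1 peak did so too, while the COX5B peak lay at the start of its gene. The low 2DG share was lost among peaks wider than the minimum (percentile 16.6). The TCA cycle had 14 of 20 genes with a 2DG promoter peak (percentile 86.9), led by PDHA1 (536), with SDHC and DLAT only in Control, and the pentose phosphate and one carbon list had 11 of 14 (94.3), led by RPIA (637).

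Genes of protein glycosylation and the stress responses of the endoplasmic reticulum had high 2DG shares that depended more on the setting. The hexosamine and N-glycosylation list had 19 of 23 genes with a 2DG promoter peak (percentile 99.4) and 8 with a Control one (97.6), a Control share that was high in 3 of 7 settings. Among peaks wider than the minimum it was 0 of 23 genes, which says little, since 105 of 20037 coding genes had a Control promoter peak there. MPI (416) was in both lists and GMPPB (362) in 2DG only, both enzymes of mannose supply, while GFPT1 (836), PMM2 (90) and ALG9 (2681) were found only in Control. The unfolded protein response list had 18 of 23 genes (97.7) in 2DG and 6 in Control. PDIA6 (796), the stress sensor kinase gene EIF2AK3 (634) and the chaperone gene HSPA5 (410) were found only in 2DG, and DNAJB11 (2279), DDIT3 (1060) and DNAJC3 (837) only in Control. As given above, single genes found only in Control say little, since Control peaks near gene ends were few beyond those of moved peaks. With equal numbers of peaks the 2DG percentiles were 96.4 for hexosamine and N-glycosylation and 72.6 for the unfolded protein response, and the 2DG share was high in 4 and 3 of 7 settings. The amino acid response list had 15 of 18 genes in 2DG (98.8), led by the transcription factor gene ATF3 (765), SLC3A2 (451) and GDF15 (410), and its call was lost among peaks wider than the minimum (74.5).

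Immediate early genes had the widest gap between the lists in the main setting, with 16 of 18 genes in 2DG (percentile 99.7) and 1, EGR1, in Control. EGR3 (473), IER3 (405) and DUSP1 (320) had a promoter peak only in 2DG, and MYC and IER5 in neither list. Among peaks wider than the minimum the 2DG percentile was 87.6, with 7 of 18 genes in 2DG and 0 in Control. The gap was then wider for the epithelial and ovarian cancer list, with 12 of 18 and 0. The epithelial and ovarian cancer list had 15 of 18 genes in 2DG (98.7) and 4 in Control, led by MUC1 (996), the Müllerian lineage factor gene PAX8 (594) and the claudin gene CLDN4 (447), with EPCAM, WFDC2 and FOLR1 in neither. Histone modifiers had high shares in both lists, 19 of 22 genes in 2DG (99.8) and 11 in Control (99.95). Besides ACSS2, whose peaks are of open origin, they were led in 2DG by the acetyltransferase gene CREBBP (321) and HDAC4 (305), and HDAC2 (2206) and HDAC8 (2081) were found only in Control. With equal numbers of peaks the 2DG percentile of this list was 78.3, and it was high in 4 of 7 settings. Among peaks wider than the minimum 1 of 22 genes had a Control promoter peak (percentile 94.3), below the limit for a high share. That setting says little on Control, where 105 of 20037 coding genes had such a peak.

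The other lists lay between the limits for a low and a high 2DG share in the main setting. Hypoxia targets had 14 of 18 genes with a 2DG promoter peak, led by MXI1 (334), with KDM3A only in Control. The AMPK and mTOR list had 12 of 18, led by STK11 (746), and the autophagy and lysosome list 12 of 19, led by LAMP1 (1183). Cell cycle genes had 15 of 23, with PCNA (264) and MCM5 (260) the strongest, DNA repair genes 14 of 21, apoptosis genes 14 of 21, with CASP9 (410), and ribosomal protein genes 14 of 22, with RPL3 (535). Mesenchymal genes had 14 of 20, led by TWIST2 (520), and polycomb-regulated developmental genes 15 of 24, led by NKX2-1 (779). The lists for other cell types and closed genes were near or below the genome's share, with 10 of 16 neuronal genes, 8 of 18 blood genes, 8 of 16 hepatocyte genes and 9 of 20 germ line and olfactory genes. Among peaks wider than the minimum the germ line and olfactory list had a low 2DG share (0 of 20 genes, percentile 0.06), and with a promoter of 3000 bp a low Control share (2 of 20, percentile 1.68). The interferon and inflammation list had 9 of 20, led by NFKBIA (395).

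**Figure D1:**
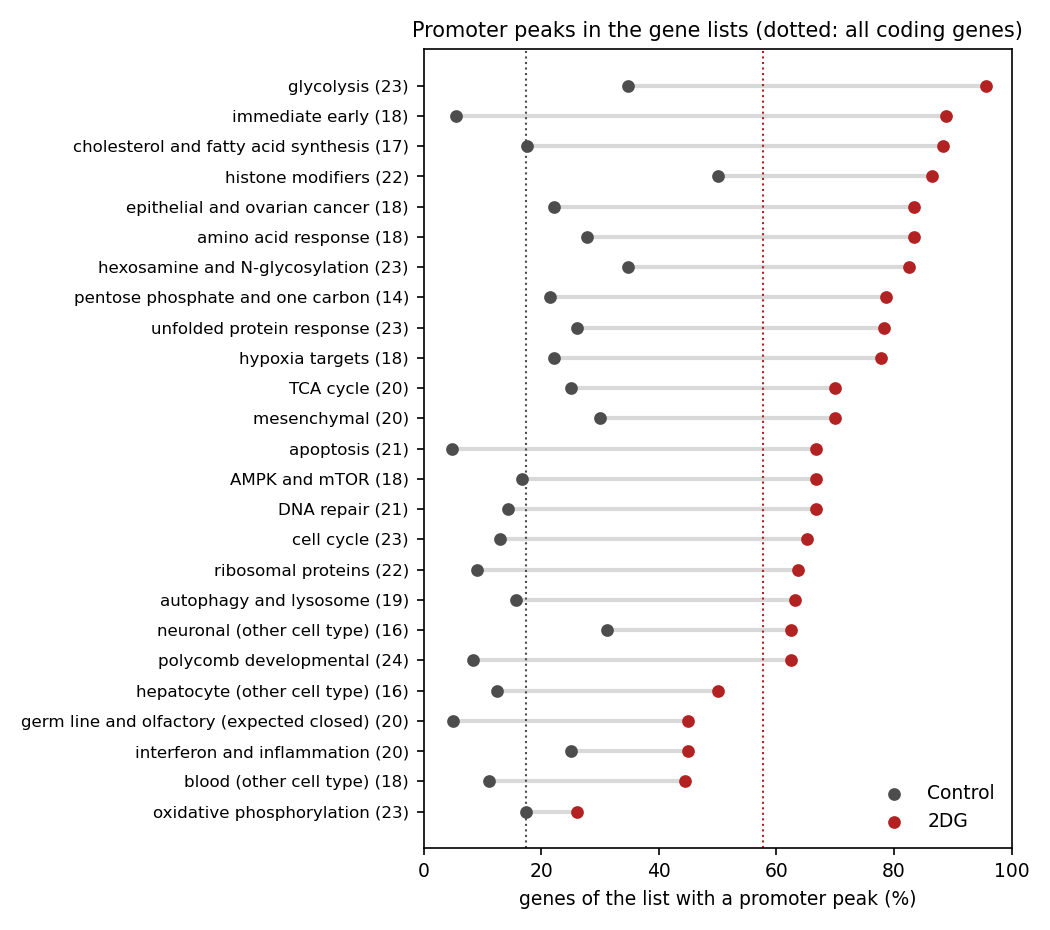
Share of the genes of each list that had a promoter peak in Control (dark points) and 2DG (red points), in percent, with the number of genes in brackets and dotted lines at the shares of all coding genes (17.4% and 57.6%). Glycolysis lies farthest to the right for 2DG at 22 of 23 genes and oxidative phosphorylation farthest to the left at 6 of 23.

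Peaks lay nearer to genes in 2DG. The promoter class held 14.7% of 2DG peaks (14.6 to 14.9) and 5.98% of Control peaks (5.81 to 6.15). Exons held 8.19% against 3.24%, transcript ends 8.40% against 4.94%, introns 43.7% against 48.2% and intergenic sequence 25.03% against 37.6%. The TSS lay within 100 bp for 6.68% of 2DG and 1.67% of Control peaks. Within 1000 bp of an end of a coding gene there were 21127 2DG peaks, 2.17 times the 9737 ± 88.4 (SD over 100 moves) found after moving the peaks, and 2733 Control peaks, 1.19 times the 2300 ± 43.8. Gene-dense chromosomes carried the largest excess of 2DG peaks. Chromosome 19 had 197 peaks per Mb in 2DG and 40.1 in Control, a ratio of 4.90, and chromosome 22 had 145 and 30.5, while chromosome 13 had 40.0 and 24.4. The outer 5 Mb of the chromosomes held 25.4% of 2DG peaks and 10.2% of Control peaks.

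**Figure D2:**
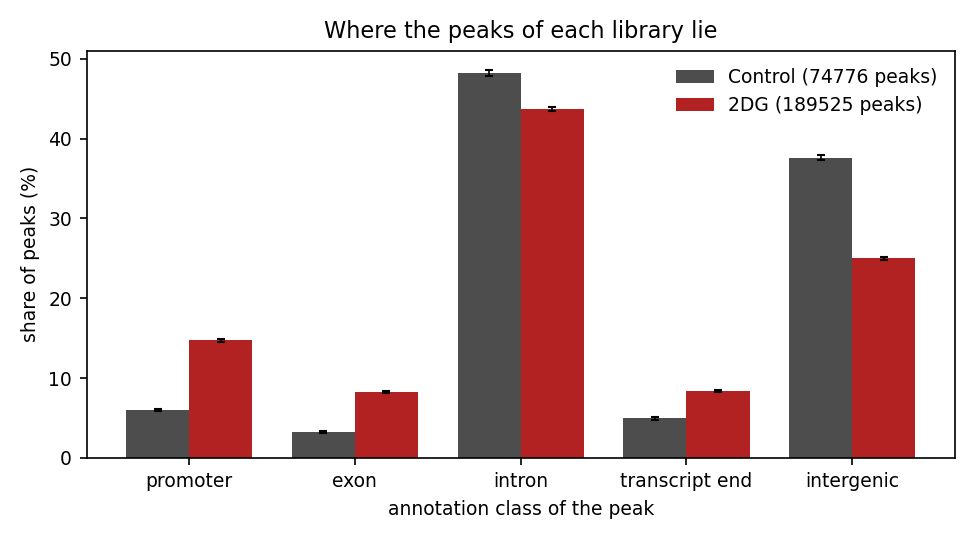
Share of the peaks of each library in each annotation class, in percent, with bars for Control (dark, 74776 peaks) and 2DG (red, 189525 peaks) and Wilson 95% intervals as error bars. The 2DG bars are higher for promoters, exons and transcript ends and lower for introns and intergenic sequence.

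The peaks covered 11.6 Mb in 2DG and 1.75 Mb in Control and were narrow in both. The minimum width was 22 bp in Control, where 96.8% of peaks had it, and 50 bp in 2DG, where 81.5% had it. Scores were spread differently, with a median of 888 (quartiles 134 and 1711) in Control and 69 (34 and 133) in 2DG. Width went with score in 2DG, from 93.8% at the minimum for scores under 50 to 7.94% for scores of 5000 or more. In Control the share at the minimum stayed between 91.9% and 99.0% up to a score of 5000 and was 22.96% above it.

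**Figure D3:**
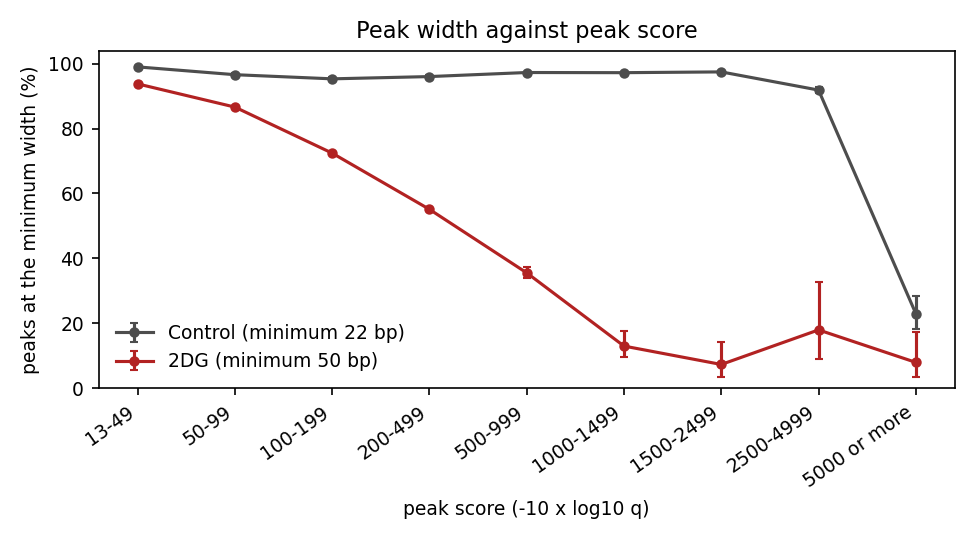
Share of peaks at the minimum width of their list, in percent, against the peak score in 9 classes, for Control (dark, minimum 22 bp) and 2DG (red, minimum 50 bp), with Wilson 95% intervals as error bars. The 2DG line runs from 93.8% to 7.94%, and the Control line stays above 90% up to a score of 5000.

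Few sites were shared. A 2DG peak touched 1311 of 74776 Control peaks (1.75%, 1.66 to 1.85), which was 3.15 times the 417 ± 20.1 found for peaks placed at random and 1.77 times the 739 ± 29.9 for peaks moved by 2 to 20 kb (SD over 100 draws). In the other direction, 1273 2DG peaks (0.672%) were touched. Promoters made up 18.7% of the shared Control peaks against 5.75% of the others, and 18.3% against 14.7% in 2DG. The share depended on the definition, since 17.3% of Control peaks had a 2DG peak within 1000 bp and 0.0642% overlapped one by at least 50% of both peaks. The last value was held down by the widths. A Control peak of 22 bp, as 96.8% were, cannot cover 50% of a 2DG peak of 50 bp or more.

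ACSS2 and a few narrow sites elsewhere were very strong in both lists. The ACSS2 gene (chromosome 20, 34874989 to 34927959) had 18 Control peaks with scores of 87487 to 542741, which made up 15 of the 20 strongest Control peaks. It had 19 peaks in 2DG, and 66.9% of the list's summed score lay there against 5.30% in Control. None of its Control peaks and 3 of its 2DG peaks were of class intron, with a highest score of 155, against a median of 1091420 for the other 16 2DG peaks. By the deposited classes, 4 Control peaks lay on exons 1, 8, 15 and 16 and 3 2DG peaks on exons 1, 15 and 16, the exon 1 peak of 2DG with a score of 7324711. The other peaks were of the promoter or transcript end class, which do not say whether a peak lies on an exon. Outside ACSS2, 10 sites scored 5000 or more in both lists. Among them were an intron of the protocadherin gene PCDH17 (chromosome 13, 57708706 to 57708783, scores 151429 in Control and 1217539 in 2DG), the FADS1 exon, and an intergenic position at -1333 bp from FOXF2 (chromosome 6, 1388205 to 1388282, scores 197150 and 331446). All 10 were 78 to 80 bp wide in 2DG and 22 to 24 bp wide in Control, with middles at most 1 bp apart.

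**Figure D4:**
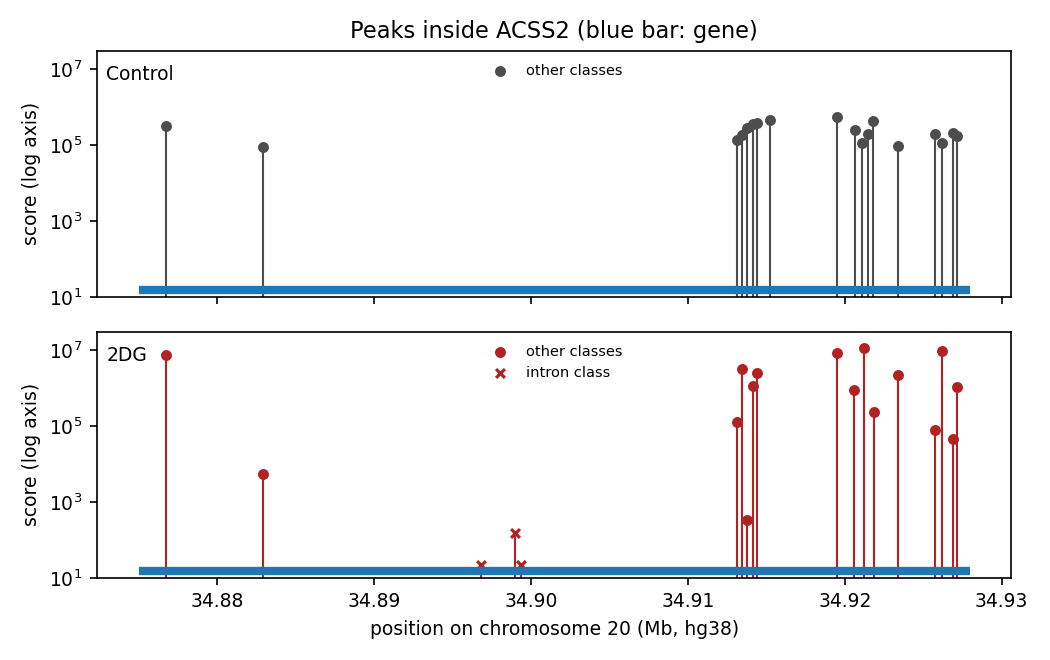
Peaks inside ACSS2 on chromosome 20, with position in Mb (hg38) on the horizontal axis and peak score on a log axis, for Control (upper panel) and 2DG (lower panel). Crosses mark the 3 intron peaks of 2DG, which reach a score of 155, and the blue bar is the gene.

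Segments of the T cell receptor beta chain were among the strongest 2DG sites. They took 16 of the 50 strongest 2DG peaks and none of the 50 strongest Control peaks. In their locus on chromosome 7 the V segments had 59 peaks in 2DG, of which 23 scored 1000 or more, and the J segments 14 peaks, of which 9 did. The orphon copies of V segments on chromosome 9 had 4 peaks in 2DG, of which TRBV20OR9-2 (33618450 to 33618513) scored 17293, beside 20768 for TRBV20-1 in the locus, and it is 1 of the 16. The highest were TRBV19 (chromosome 7, 142619472 to 142619534, class transcript end, score 35862), TRBV28 (25798) and TRBJ2-1 (21463). These segments are near-identical copies in part, so the assignment of peaks to single segments is uncertain. In Control the V segments had 7 peaks in the locus, of which 6 scored 1000 or more, with a highest score of 3100, and 7 peaks at the orphons, of which 2 did. Immunoglobulin heavy chain V segments, orphons included, had 106 peaks in 2DG, of which 11 scored 1000 or more, all of class transcript end, with a highest score of 4076, and 89 peaks in Control, of which 12 did. Such scores were held by 0.247% of all 2DG peaks and 46.6% of all Control peaks.

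Loci known for copy number changes or loss in SKOV3 did not stand apart. ERBB2, amplified in this line, had 18 2DG peaks and 4 Control peaks within 10 kb of the gene, at percentiles 83.9 and 88.2 among 1000 windows of similar genes. Its neighbours GRB7 and MIEN1 had 7 2DG peaks each (percentiles 64 and 71.4). CDKN2A had 4 2DG and 3 Control peaks (45.2 and 83.9) and MTAP 3 and 4 (17.3 and 52.9), both listed beforehand as lost in this line. CDKN2A had a promoter peak in both lists, and a Control peak of score 2938 lay within 10 kb of it, while MTAP had a promoter peak in 2DG. The loss itself was not measured, and peaks were not separated from background here.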

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

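The settings with peaks wider than the minimum and with matched random lists were chosen after the data were seen. With 1 library per group neither a replicate could be left out nor a spread measured, and the unknown depth limits every comparison of peak numbers and of genes with or without a peak. No paired analysis was possible because each group has 1 library and no test was made. The alternative of a fold enrichment of at least 4 was not run, since the lists hold no fold enrichment. Named genes apart, of the 59 values under settings fixed beforehand, 36 stayed within their interval or within 1.5 times the main count, and of the 24 under added settings 6 did. Some of the 36 could not move. Equal numbers left the Control list unchanged, and using all sequences left both lists unchanged. Under every setting that gave both values, the 2DG list had more peaks (or, by construction, as many), a larger covered length, a higher promoter share and more genes with a promoter peak. The covered length is not a separate result, since the minimum width was 50 bp in 2DG and 22 bp in Control and 2DG had at least as many peaks.

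With scores of at least 50, 2DG had 118490 peaks with a median score of 109, the promoter shares were 6.29% in Control and 15.9% in 2DG, and 1.35% of Control peaks were shared. With equal numbers, 2DG had 74776 peaks covering 5.23 Mb with a median score of 157 and a promoter share of 16.6%, the shared parts were 0.975% of Control and 0.924% of 2DG peaks, 7504 genes had a 2DG promoter peak, 1583 a Control one only and 5602 a 2DG one only, and 5 gene lists had a high 2DG share. The smaller numbers of 2DG peaks, covered bases and genes with a 2DG promoter peak follow from keeping fewer peaks. Why fewer gene lists had a high 2DG share was not tested. With peaks wider than the minimum, 2425 Control and 35022 2DG peaks remained, covering 0.160 and 3.86 Mb, with promoter shares of 9.24% and 22.1%, shared parts of 6.52% and 0.423%, and a median 2DG score of 146. Then 105 genes had a Control and 5292 a 2DG promoter peak, 43 both, 62 only Control and 5249 only 2DG, and high shares were found for 2 gene lists in 2DG, 2 among genes only in 2DG and 1 in Control. Over peaks moved by 2 to 20 kb, the shared number was 1.86 times at scores of at least 50, 1.88 times with equal numbers and 3.31 times among wider peaks.

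Overlap of at least 50% of both peaks gave shared parts of 0.0642% of Control and 0.0253% of 2DG peaks, and a distance within 1000 bp gave 17.3% and 9.32%. The first 2 values were held down by the widths, since Control peaks of 22 bp cannot cover 50% of a 2DG peak. By distance to the TSS, 9.73% of Control and 23.03% of 2DG peaks lay within 1000 bp. A promoter of 3000 bp gave 6237 genes in Control and 5017 in both lists. Matching random lists on RefSeq transcripts left 1 list with a high Control share. Over 7 settings, glycolysis and the epithelial and ovarian cancer list had a high 2DG share in 7, and oxidative phosphorylation a low one in 6. The 29 genes named as strongest in a peak list, or as strongest of those found in 1 peak list only, were followed across settings. A promoter peak in the same lists was found for 29 at scores of at least 50, 28 with equal numbers (without COX7A2L), 27 with a promoter of 3000 bp (without ADIPOR2 and RNF213), 29 with distances from the middle of a peak and 19 among wider peaks. Genes named from the gene lists were not followed, and of these ATP5PO had a Control score of 49, under that limit of 50. Where a value moved and no construction is named, the cause was not tested.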

Other observations

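Gene families, chosen after the data were seen, differed widely in their 2DG promoter peaks. A peak was present at 44 of 392 olfactory receptor genes (11.2%, below all 10000 random lists with and without matching on gene length or transcripts), 3 of 39 beta-defensin genes, 5 of 28 taste receptor genes, 11 of 53 clustered protocadherin genes and 20 of 80 histone genes (25%). Most of these families were low in Control too, without matching. There 21 olfactory receptor genes (percentile 0), 1 beta-defensin (0.26), 2 protocadherin (0.17) and 5 histone genes (0.225) had a peak. Taste receptor genes were not below the limit in Control (2 genes, 7.10). At the other end, 257 of 386 solute carrier genes (66.6%, percentile 99.98, 99.5 after matching on transcripts) and 18 of 22 NKX and LHX homeobox genes (81.8%, percentile 99.0) had one. Zinc finger genes of the ZNF series had 277 of 517 in 2DG, at percentile 3 and at 0.085 after matching on transcripts, and 54 of 517 in Control (percentile 0, without matching). In Control, collagen genes had the highest percentile of the 23 families without matching, with 15 of 44 genes (99.65). The share of coding genes with a Control promoter peak was 7.53% in the shortest of 10 length classes and 24.7% in the longest. In 2DG the collagen percentile fell from 86.3 to 63.8 after matching on gene length. Control percentiles of families were not matched, so whether the collagen share is high for genes of such length was not tested. None of the 40 HOX genes had a promoter peak in Control, against 18 in 2DG. The fullest 1 Mb windows were chromosome 21 from 8 to 9 Mb in Control (299 peaks) and chromosome 9 from 136 to 137 Mb in 2DG (762 peaks).

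Of the tests that follow, those of stacked fragments, gene ends as the whole cause, spliced DNA, binding along ACSS2 and the 3 on the T cell receptor were chosen only after the result was seen.

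Control peaks kept the minimum width of 22 bp up to a score of 5000. The minimum-width peaks were not crowded into few windows, as the 1% fullest windows of 1 Mb held 3.34% of them. Repeats near centromeres and ribosomal DNA stay open, since those windows were picked by peak number and positions of repeats were not used. Focused binding at gene ends in the untreated cells is argued against as the whole cause, as 3.68% of the minimum-width peaks lay within 1000 bp of a gene end. The excess of Control peaks over moved peaks was 1.19 ± 0.032 times, a spread that combines the counting error of the observed number with the SD over moves. A small part of the peaks at gene ends stays open, because that excess lies within its spread of the limit of 1.2 set beforehand. Stacks of copies of few DNA fragments stay open and without support, since the share of Control peaks with a score of 1000 or more at the minimum width, 96.3%, restates the pattern, and read ends and the handling of duplicates are unknown.

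No strong ACSS2 peak was of class intron in either list. Extra genomic copies that reach beyond the gene have little support, as the highest score within 100 kb was 0.890% of the median of the gene's other peaks in the list where it was higher. Copies of the gene alone stay open, since its flanks cannot show them and a score does not measure copy number. The flanks had 175 peaks per Mb in 2DG, against 102 on the chromosome, and 35 against 31.5 in Control. Spliced ACSS2 sequence from outside the chromosome, such as complementary DNA, and binding to chromatin along the gene both stay open. The intron peaks' share of the summed score, 0.000414%, and their highest score, 0.0142% of that median in 2DG, restate the pattern and decide neither. The deposited classes place 4 Control and 3 2DG peaks on exons, and for the others, of the promoter and transcript end classes, exon coordinates were not used here.

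The T cell receptor beta segments carried high scores in 2DG. T cells in the culture are argued against, as 0 of the 2DG peaks at alpha chain segments reached a score of 1000, CD3D, CD3E and PTPRC had no 2DG promoter peak, and the blood list stood at percentile 13.4 with 8 of 18 genes in 2DG. Rearranged receptor sequence from another library stays open and without support, since the place of the V segment peaks with a score of 1000 or more, 100% at the 3′ end of the segment, is what raised it. Reads shared between similar segments stay open too, as the chromosome 9 orphon TRBV20OR9-2 scored 17293 beside TRBV20-1 at 20768, while 4.89% (2.75 to 8.54) of 2DG peaks at other receptor chains reached 1000, an interval that spans the limit of 5%. Those were 11 of 106 peaks (10.4%) at immunoglobulin heavy chain V segments, also at the 3′ end, and 0 of 119 at the alpha and light chain segments, and no biological explanation, which the design does not name, was tested.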
